A study of Homo sapiens with 9 samples.

How the data were processed

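Total RNA from 9 samples of MCF10A cells, 3 each with a scramble control, RND1 hairpin sh-34 and RND1 hairpin sh-35, was extracted with Trizol, labelled as biotinylated cRNA and hybridized to Illumina bead arrays, per the labels. The submitters' processing notes name BeadStudio and Partek, and the versions are not given in the sources used here. The cells had been infected with lentivirus and selected with puromycin; the labels do not state the time of harvest or whether the samples of a group were separate cultures. Hairpin sequences are not given in the sources used here.

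Several kinds of deposited values were used. The deposited signal table holds an intensity for each of 48803 probes and each sample, per the file headers, together with a detection p-value. Medians of the deposited intensity differed between arrays, so the values had been neither quantile normalized nor scaled to a common median. No value was below 0, so they were taken as not background subtracted. Whether another scaling between arrays had been applied cannot be told from the values. The deposited series matrix holds log2 values. Each is the log2 of the same signal less the probe's median over the 9 samples plus a constant of 5.62. No further normalization between arrays had been applied, and the values per sample had medians of 5.57 to 5.74. A further deposited table lists 358 probes with, for each hairpin, the authors' unadjusted p-value, a ratio of geometric means against scramble and a signed fold change. The authors' ratio and p-value were recomputed from the deposited signals with largest relative departures of 3.43e-06 and 0.00414. Of the probes on the array, the 358 listed by the authors were those with at least a 1.4-fold change and a contrast p-value of at most 0.00111 for sh-34 and 0.00175 for sh-35. The remaining columns of the authors' table, a score for the analysis of variance and its sums of squares, were not used here.

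Probes were named from an annotation table of the array and from RefSeq gene names. A single symbol was given for 28098 probes, several for 13, and 20692 probes were not listed. The Entrez identifiers of 28059 probes matched, and 0 symbols needed updating. Coordinates are not given because no deposited table names a genome build.

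Signals were corrected for background with limma's normal-exponential model, its noise estimated from the detection p-values, with an offset of 16, and were then quantile normalized on the log2 scale. Probes with a detection p under 0.01 in at least 3 of the 9 arrays were tested, 12866 in all. For each of 8931 genes the probe with the highest mean log2 signal was kept. One limma model with 3 groups was fitted to all 9 samples, with 6 residual and 5.42 prior degrees of freedom. From it came sh-34 minus scramble, sh-35 minus scramble, the mean of both minus scramble, and sh-35 minus sh-34. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. No pairing was used, since replicate numbers did not link samples of different groups: deviations from the group mean correlated across genes by −0.0141 to 0.0590 for equal numbers. Where a gene was above background on no array of a group, the fold is a lower bound, set against the lowest level called above background, and no fold is given where both groups were below it. The exact permutation test planned for RND1, whose smallest p for 3 against 3 samples is 0.1, was not made because the probe was below background.

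Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. There were 30 lists of pathways and cell states and 5 lists of markers of other cell types. Of these, 32 had at least 3 tested members. Camera with an estimated correlation and fry were run as alternatives. Members were counted by the gene test over all genes and again adjusted over the list alone. The excess of genes shared by both hairpins was set beside 100 simulations of unchanged groups with a shared control.

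Named genes followed a rule. It took RND1, the 10 largest rises and 10 largest falls shared by both hairpins (by the smaller of the absolute changes), the 5 largest rises and falls for each hairpin and between the hairpins, up to 6 members of each list with the smallest p, a set of genes chosen for adhesion, mesenchymal state, ERK output and RND signalling, and the 5 genes at each end of the authors' fold changes. Not every list member the rule allows is named, and the results of 1 gene list and 1 gene of the rule are not reported. Groups, comparisons and their tests, lists, the naming rule and all alternatives but 6 were set before the data were examined; the tests of explanations for the cell cycle and interferon genes were not.

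Alternatives covered cyclic loess and median scaling in place of quantile normalization, an offset of 50, no background correction, the series matrix values, other filters on dim probes, the mean of a gene's probes and every probe on its own, limma with trend and robust options and without moderation, only the groups compared, the replicate number as a block, folds of at least 1.5 and 2, and each replicate left out in turn.

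The procedure was tested on simulated data with 8931 genes and 3 samples per group. It recovered 77.8% of 1.5-fold, 95.3% of 2-fold and 100% of 4-fold changes for sh-34 against scramble, and 75.5%, 93.3% and 100% for sh-35. Of the genes called, 6.87% were false for sh-34, 9.27% for sh-35, 7.45% for the mean of both and 4.79% between the hairpins, so the share was above the nominal rate of 0.05 in 3 of the 4 comparisons. A simulated list of 30 genes raised 1.5-fold with sh-35 had a camera p of 1.6e-47 there and of 0.869 with sh-34, where it was unchanged. In the simulation 131 to 161 genes were called per comparison, against 3347 to 3814 in the data, so these rates may not carry over. Its noise was independent between genes, so the camera p-values hold for a list of uncorrelated members.

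Computations used R 4.3.3 with limma 3.58.1, and figures used Python 3.11.15 with matplotlib 3.10.9.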

Results

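Gene expression was measured with Illumina bead arrays in MCF10A cells, an immortalized, non-tumorigenic human mammary epithelial line. The cells had been infected with lentivirus carrying a short hairpin RNA against RND1 or a scramble control, and infected cells were selected with puromycin. RND1 encodes a small GTPase that acts on the actin cytoskeleton and on plexin signalling. The samples formed 3 groups of 3, scramble, RND1 hairpin sh-34 and RND1 hairpin sh-35, 9 samples in all. Each array carried 48803 probes, of which 11473 to 12902 (23.5% to 26.4%) were above background at a detection p under 0.01. The median deposited signal per array lay between 46.6 and 53.4. After normalization, Pearson's r across genes was 0.992 to 0.994 within groups and 0.962 to 0.974 between groups (genes are not independent replicates). The first principal component held 46.1% of the variance and the second 33.3%. Of the probes, 12866 were tested, and they gave 8931 named genes with 1 probe each. The median within-group SD was 0.12 on the log2 scale. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of each value.

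The level of RND1 itself, the target of both hairpins, could not be measured. Its only probe was above background on 0 of the 9 arrays. The probe's signals ran from 27.7 to 49.6, and its lowest detection p was 0.165, whereas the dimmest probe signal called above background on any array was 110.1. No fold change is given for RND1, and the loss of its transcript with either hairpin could not be checked. Probes for SNAI1, ZEB1 and RND2 were likewise above background on 0 arrays, and RASA1 had no named probe here. RND3, a close relative of RND1, was measurable and fell with both hairpins, by −0.61 (SE 0.11; limma adjusted p = 0.0012) with sh-34 and −0.79 (SE 0.11; adjusted p = 0.00014) with sh-35. PLXNB1, which encodes a plexin receptor that binds RND proteins, read +0.05 and −0.21 (SE 0.12 each) and did not pass the threshold with either hairpin.

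The first comparison asked what changed when cells carried sh-34 in place of the scramble control. IL1B, the inflammatory cytokine interleukin-1 beta, fell from 12.32 ± 0.10 (SD, n = 3) to 9.61 ± 0.03 on the log2 scale. Its log2 change was −2.72 (SE 0.10; limma adjusted p = 3.5e-08), the largest fall among the tested genes. HAS3, a hyaluronan synthase, fell by 2.45 on the log2 scale (SE 0.15), and FOLR3, a secreted folate receptor, fell by 2.36 (SE 0.13). WDR7 dropped below background, at least 2.52-fold lower than in scramble, and MOB3B was at least 2.07-fold lower. KLRC3 and KLRC2, natural killer cell receptor genes, rose by +2.69 (SE 0.10) and +2.40 (SE 0.12), although their sequences are so alike that the probes may not tell them apart. NWD1 was at least 2.05-fold higher than in scramble, SCNN1B, a subunit of the epithelial sodium channel, at least 1.70-fold higher, and LAPTM5, a lysosomal membrane protein gene, at least 1.39-fold higher. The scramble arrays held no signal above background for these last 3 genes.

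Keratinocyte differentiation genes fell as a group with sh-34. Of 16 tested, 14 fell, 0 rose and 2 did not pass (14 lower and 1 higher adjusted over the list alone), with a median log2 change of −0.87, or −0.82 with undetected members at their bound. Its camera adjusted p was 3.2e-07 (adjusted p = 0.0783 with an estimated correlation). KRT6C fell by 1.02 on the log2 scale (SE 0.09), KRT16 by 0.92 (SE 0.10), and PI3, a protease inhibitor of squamous epithelium, by 0.90 (SE 0.10). Histone genes rose, 13 of 19 higher, 0 lower and 6 not past the threshold (14 higher and 1 lower adjusted over the list alone). The histone median was +0.81, or +0.40 with undetected members at their bound, and the camera adjusted p of 5.9e-07 held at 0.0313 with an estimated correlation. H4C8 rose by +1.60 (SE 0.10), H2BC21 by +1.39 (SE 0.09), and H1-2 by +1.30 (SE 0.09), while H2BC8 was at least 2.32-fold higher. Without the filter on dim probes, which lets in members not above background, the median was −0.0687 for keratinocyte differentiation and +0.35 for histone genes, and both calls held.

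Cell cycle and mitosis genes also rose with sh-34. Of 47 tested, 27 rose, 1 fell and 19 did not pass (31 and 1 adjusted over the list alone), with a median of +0.30 (camera adjusted p = 2.2e-06; adjusted p = 0.127 with an estimated correlation). CENPF, a kinetochore protein gene, rose by +0.80 (SE 0.10), and TOP2A, encoding a DNA topoisomerase, by +0.77 (SE 0.08). Genes of Ras-ERK output, whose transcription ERK signalling raises, fell, 12 of 20 lower, 0 higher and 8 not past (14 lower and 1 higher adjusted over the list alone). Their median was −0.33 (camera adjusted p = 4.5e-05; adjusted p = 0.127 with an estimated correlation). HBEGF and TGFA, both ligands of the EGF receptor, fell by 1.19 (SE 0.09) and 0.93 (SE 0.08) on the log2 scale, and the transcription factor gene ETV4 fell by 0.88 (SE 0.10). Cyclin D1, CCND1, fell by 0.99 (SE 0.08; limma adjusted p = 6.8e-06), and the ERK phosphatase gene DUSP6 fell by 0.43 (SE 0.10; adjusted p = 0.0047).

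Epithelial markers fell with sh-34. Among 19 epithelial junction genes, 9 fell, 2 rose and 8 did not pass (9 and 2 adjusted over the list alone), with a median of −0.27 (camera adjusted p = 0.0084; adjusted p = 0.118 with an estimated correlation). CDH1, encoding E-cadherin, went from 11.60 ± 0.05 to 10.83 ± 0.11 (SD, n = 3), a log2 change of −0.76 (SE 0.09; limma adjusted p = 5.6e-05). DSC2, a desmosomal cadherin gene, fell by 1.22 on the log2 scale (SE 0.09), and the membrane protease gene PRSS8 by 1.54 (SE 0.10). Basal mammary markers had 9 of 12 lower, 2 higher and 1 not past (9 and 2 adjusted over the list alone), with a median of −0.54 (camera adjusted p = 0.0025; adjusted p = 0.118 with an estimated correlation). KRT14, a basal keratin, fell by 1.84 on the log2 scale (SE 0.07). Luminal markers had 7 of 12 lower, 2 higher and 3 not past (8 lower and 3 higher adjusted over the list alone), with a median of −0.46, or −0.37 with the undetected member at its bound. The luminal camera adjusted p was 0.0268 (adjusted p = 0.170 with an estimated correlation), and its call was lost without the filter on dim probes (adjusted p = 0.130). ALDH1A3 and KRT15 fell by 1.49 (SE 0.10) and 1.42 (SE 0.14), while MUC1 rose by +1.08 (SE 0.14). Without that filter the median was −0.15 for junction genes and −0.0646 for luminal markers.

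Lipid and glucose metabolism genes fell as well with sh-34. Cholesterol and fatty acid synthesis had 12 of 25 lower, 0 higher and 13 not past (12 and 0 adjusted over the list alone), with a median of −0.26 (camera adjusted p = 0.00070; adjusted p = 0.201 with an estimated correlation). ACLY, which makes acetyl-CoA for lipid synthesis, fell by 1.11 on the log2 scale (SE 0.10). The hypoxia and glycolysis list had 13 of 31 lower, 4 higher and 14 not past (13 and 4 adjusted over the list alone), with a median of −0.17 (camera adjusted p = 0.0109; adjusted p = 0.128 with an estimated correlation). Hexokinase 2, HK2, fell by 1.10 (SE 0.14), while the glucose transporter gene SLC2A3 rose by +0.65 (SE 0.10).

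Among genes named beforehand for the mesenchymal state, VIM rose by +0.49 with sh-34 (SE 0.08; limma adjusted p = 0.00087). CDH2, FN1, SNAI2 and TWIST1 did not pass, at +0.13, −0.27, +0.17 and +0.23. The list of mesenchymal genes had 5 of 18 higher, 3 lower and 10 not past (6 and 3 adjusted over the list alone; camera adjusted p = 0.452). Interferon response genes were not called with sh-34 either, with 11 of 28 higher, 3 lower and 14 not past (11 and 3 adjusted over the list alone; camera adjusted p = 0.224). A second FN1 probe, however, read −0.70 and passed (adjusted p = 0.0019). CDKN1A, a cyclin-dependent kinase inhibitor gene, fell by 0.41 on its brighter probe (SE 0.07; adjusted p = 0.0011), but its other probe read +0.34, and the mean of both gave an adjusted p of 0.749. SPRY2, FOSL1 and ETV5, targets of ERK signalling, did not pass, at −0.20, −0.07 and −0.18. RRAS read +0.38 (adjusted p = 0.0044), a call lost with median scaling (adjusted p = 0.0639) and with the series matrix values (0.0962).

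In all, 3347 of 8931 genes (37.5%) passed an adjusted p of 0.05 with sh-34 in limma, 1693 higher and 1654 lower. At least a 2-fold change was fitted for 258 of them, 110 higher and 148 lower. The share of changed genes that were higher was 50.6% after quantile normalization, 39.4% after median scaling and 37.8% in the series matrix values, so the balance of rises and falls rests on the scaling.

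The second comparison asked the same of sh-35. TAGLN, which encodes the actin-binding protein transgelin, fell from 12.58 ± 0.10 to 9.24 ± 0.07 (SD, n = 3), a log2 change of −3.34 (SE 0.09; limma adjusted p = 1.4e-09) or 10.1-fold. Falls on the log2 scale followed in TMEM9B (−2.57, SE 0.11), IL1B (−2.38, SE 0.10), the epithelial polarity gene CRB3 (−2.21, SE 0.09) and FOLR3 (−2.11, SE 0.13). SERPINA5, a protease inhibitor gene, was at least 3.88-fold higher than in scramble, and the interferon-induced gene IFI44L at least 3.02-fold higher. LOX, an enzyme that crosslinks collagen, rose by +2.25 (SE 0.10), KLRC3 by +2.22 (SE 0.10), and the acute-phase gene SERPINA3 by +2.22 (SE 0.10).

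Cell cycle and mitosis genes rose almost without exception with sh-35. Of 47 tested, 46 rose, 0 fell and 1 did not pass (46 and 0 adjusted over the list alone), with a median log2 change of +1.16. The camera adjusted p was 2.1e-28, and the call held with an estimated correlation (adjusted p = 0.0137). HMMR, a mitotic spindle gene, rose by +2.03 (SE 0.12), TOP2A by +1.79 (SE 0.08), CENPF by +1.75 (SE 0.10) and CCNB2, a mitotic cyclin gene, by +1.63 (SE 0.08). Interferon response genes rose, 21 of 28 higher, 1 lower and 6 not past (22 and 1 adjusted over the list alone), with a median of +0.60 (camera adjusted p = 5.4e-08; adjusted p = 0.124 with an estimated correlation). IFIT1 rose by +1.89 (SE 0.14), IFI44 by +1.64 (SE 0.12) and IFIT3 by +1.62 (SE 0.13), all known interferon-induced genes.

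Epithelial junction genes fell with sh-35, 15 of 19 lower, 1 higher and 3 not past (15 and 1 adjusted over the list alone). Their median was −0.70, or −0.69 with the undetected member at its bound, and the camera adjusted p of 1.7e-07 held with an estimated correlation (adjusted p = 0.0137). CDH1 fell from 11.60 ± 0.05 to 9.74 ± 0.11 (SD, n = 3), a log2 change of −1.85 (SE 0.09; limma adjusted p = 1.1e-07). EPCAM, an epithelial adhesion molecule gene, fell by 1.88 on the log2 scale (SE 0.08), and JUP, encoding the junction protein plakoglobin, by 1.26 (SE 0.09). The actin cytoskeleton list had 14 of 28 lower, 3 higher and 11 not past (14 and 3 adjusted over the list alone), with a median of −0.21 (camera adjusted p = 0.0075; adjusted p = 0.267 with an estimated correlation). Tropomyosin gene TPM4 fell by 1.04 (SE 0.10), and MYL9, a myosin light chain gene, was at least 2.28-fold lower. Basal markers had 7 of 12 lower, 1 higher and 4 not past (7 and 1 adjusted over the list alone), with a median of −0.31 (camera adjusted p = 0.0102; adjusted p = 0.124 with an estimated correlation). Luminal markers had 8 of 12 lower, 2 higher and 2 not past (8 and 2 adjusted over the list alone), with a median of −0.58. The luminal camera adjusted p was 0.0227 (adjusted p = 0.166 with an estimated correlation), and without the filter on dim probes it was 0.0574. Without that filter the median was −0.33 for junction genes, −0.19 for basal markers and −0.0984 for luminal markers, and with median scaling the actin median was −0.35.

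Metabolic and stress groups moved in both directions with sh-35. Cholesterol and fatty acid synthesis had 17 of 25 lower, 1 higher and 7 not past (18 and 2 adjusted over the list alone), with a median of −0.42 (camera adjusted p = 0.00053; adjusted p = 0.189 with an estimated correlation), and MVD, of the mevalonate pathway, fell by 0.84 (SE 0.13). Hypoxia and glycolysis genes had 17 of 31 lower, 2 higher and 12 not past (18 and 3 adjusted over the list alone), with a median of −0.27 (camera adjusted p = 0.0040; adjusted p = 0.124 with an estimated correlation). PFKFB3, a regulator of glycolysis, fell by 1.04 on its brighter probe (SE 0.08), while its other probe read −0.33 and did not pass (adjusted p = 0.0858). The metallothionein list had 4 of 6 higher, 0 lower and 2 not past (4 and 0 adjusted over the list alone). Its median was +0.43 (camera adjusted p = 0.0165, or 0.124 with an estimated correlation). It holds metallothioneins, close paralogs that bind metal ions, and the zinc transporter gene SLC30A1, which did not pass with sh-35. MT1X rose by +1.52 (SE 0.09). The metallothionein median was +0.23 without the filter on dim probes.

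The list named senescence regulators had 6 of 8 higher, 1 lower and 1 not past with sh-35 (6 and 1 adjusted over the list alone), with a median of +0.49 (camera adjusted p = 0.0227; adjusted p = 0.194 with an estimated correlation). The median of this list was +0.16 without the filter on dim probes. CDKN1B, which restrains the cell cycle, rose by +1.05 (SE 0.10) and the chromatin protein gene HMGA2 by +0.70 (SE 0.09). LMNB1, a nuclear lamina gene known to be lost in senescent cells, rose by +1.44 (SE 0.14), and CDKN1A fell by 0.53 on its brighter probe (SE 0.07; limma adjusted p = 0.00013), while its other probe read −0.10.

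Secreted and mesenchymal gene lists rose with sh-35 by a small margin. Secreted proteases and inhibitors had 10 of 22 higher, 0 lower and 12 not past (10 and 0 adjusted over the list alone), with a median of +0.30 (camera adjusted p = 0.0241; adjusted p = 0.124 with an estimated correlation). PLAT, encoding tissue plasminogen activator, rose by +0.62 (SE 0.11). Mesenchymal genes of epithelial-mesenchymal transition had 9 of 18 higher, 1 lower and 8 not past (9 and 1 adjusted over the list alone), with a median of +0.18 (camera adjusted p = 0.0316; adjusted p = 0.350 with an estimated correlation). S100A4 rose by +0.90 (SE 0.08) and the receptor kinase gene AXL by +0.84 (SE 0.11). The 1 lower member of this list was TAGLN, at −3.34. Inflammatory and secretory genes of the NF-kB pathway had 11 of 19 higher, 3 lower and 5 not past (11 and 3 adjusted over the list alone), with a median of +0.39 (camera adjusted p = 0.0456; adjusted p = 0.235 with an estimated correlation). CXCL1, a chemokine gene, rose by +1.18 (SE 0.10), while IL1A, like IL1B, fell, by 0.84 (SE 0.07). The protease call was lost with median scaling (adjusted p = 0.0624) and with the series matrix values (0.0716), and the mesenchymal call with these settings (0.0624 and 0.0828), without scramble replicate 1 (0.0819) and without scramble replicate 3 (0.0530). The NF-kB call was lost with the series matrix values (adjusted p = 0.0574), without sh-34 replicate 3 (0.0502) and without sh-35 replicate 1 (0.0818). The protease and NF-kB medians were +0.12 and +0.21 without the filter on dim probes.

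Some lists that changed with sh-34 were not called with sh-35. Ras-ERK output had 9 of 20 lower, 2 higher and 9 not past (9 and 2 adjusted over the list alone), with a median of −0.10 (camera adjusted p = 0.157). HBEGF fell by 1.99 on the log2 scale with sh-35 (SE 0.09), PHLDA1 by 0.90 (SE 0.09) and DUSP6 by 0.38 (SE 0.10; limma adjusted p = 0.0075), while CCND1 read +0.09 (adjusted p = 0.41). Keratinocyte differentiation genes had 8 of 16 lower, 4 higher and 4 not past (9 and 4 adjusted over the list alone; camera adjusted p = 0.157), and histone genes 7 of 19 higher, 4 lower and 8 not past (8 and 4 adjusted over the list alone; camera adjusted p = 0.539). Of the mesenchymal genes named beforehand, TWIST1 rose by +0.43 (SE 0.09; adjusted p = 0.0020), and CDH2 read +0.11 (adjusted p = 0.37). VIM read +0.36 (adjusted p = 0.0048), a call lost with median scaling (0.125) and with the series matrix values (0.0989), though its second probe, also at +0.36, passed (0.0163), and FN1 read +0.52 (adjusted p = 0.010), a call lost without moderation (0.0545), while its second probe read +0.27 and did not pass (0.136). Of SNAI2, at +0.31 (adjusted p = 0.037), the call was lost in 11 alternatives, with adjusted p from 0.0569 to 0.382, while its second probe read +0.38 and passed (0.0091). SPRY2 read +0.29 (adjusted p = 0.035), lost in 9 alternatives with adjusted p from 0.0551 to 0.134. FOSL1, ETV5 and RRAS did not pass, at +0.21, +0.15 and −0.11.

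With sh-35, 3731 of 8931 genes (41.8%) passed the threshold in limma, 1821 higher and 1910 lower. A fitted change of at least 2-fold was found in 456, 283 higher and 173 lower. The share of changed genes that were higher was 48.8%, against 40.9% after median scaling.

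The third comparison asked what both hairpins had in common, since hairpins of different sequence against the same target are usually read together. CD14, a co-receptor for bacterial lipopolysaccharide, rose from 7.99 ± 0.05 (SD, n = 3) to 9.80 ± 0.08 with sh-34 and 9.67 ± 0.08 with sh-35 (limma adjusted p = 9.3e-08 and 1.1e-07). IL1B fell from 12.32 ± 0.10 to 9.61 ± 0.03 and 9.94 ± 0.19 (adjusted p = 3.5e-08 and 6.1e-08). The 10 genes with the largest shared rise also included KLRC3, KLRC2, CRACDL (+1.44 and +1.76 with sh-34 and sh-35) and LINC01451 (+1.48 and +1.41). ETNK2, SYTL3 and SCNN1B, not above background in scramble, were at least 1.65-fold, 1.84-fold and 1.70-fold higher with sh-34 and at least 1.5-fold, 1.83-fold and 1.26-fold higher with sh-35. MAMDC2, also not above background in scramble, was at least 1.38-fold higher with sh-35, and its bound with sh-34 was 1.00-fold. The shared falls were led by IL1B, FOLR3, CA2, a carbonic anhydrase gene (−1.79 and −1.5), KIF3B, a kinesin motor gene (−1.94 and −1.48), HAS3 (−2.45 and −1.49), GPRC5A (−1.74 and −1.51) and PRSS8 (−1.54 and −1.36). KRT34, SERPINB13 and FCRLA dropped below background with both hairpins, by at least 1.51-fold, 1.47-fold and 1.66-fold with sh-34 and 1.48-fold, 1.45-fold and 1.63-fold with sh-35.

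**Figure D1:**
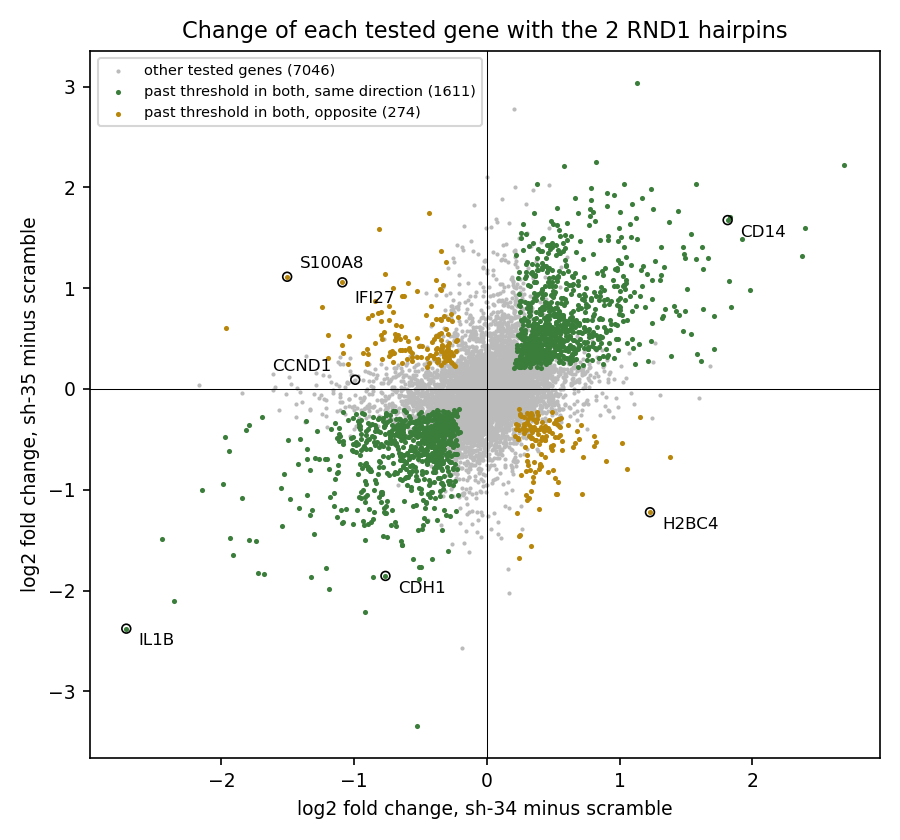
Log2 fold change of each of 8931 tested genes with sh-34 (x axis) and with sh-35 (y axis), both against scramble, with 1611 genes past the threshold in the same direction in green and 274 in opposite directions in gold. IL1B lies at −2.72 and −2.38, CD14 at +1.81 and +1.68, and S100A8 at −1.5 and +1.11.

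**Figure D2:**
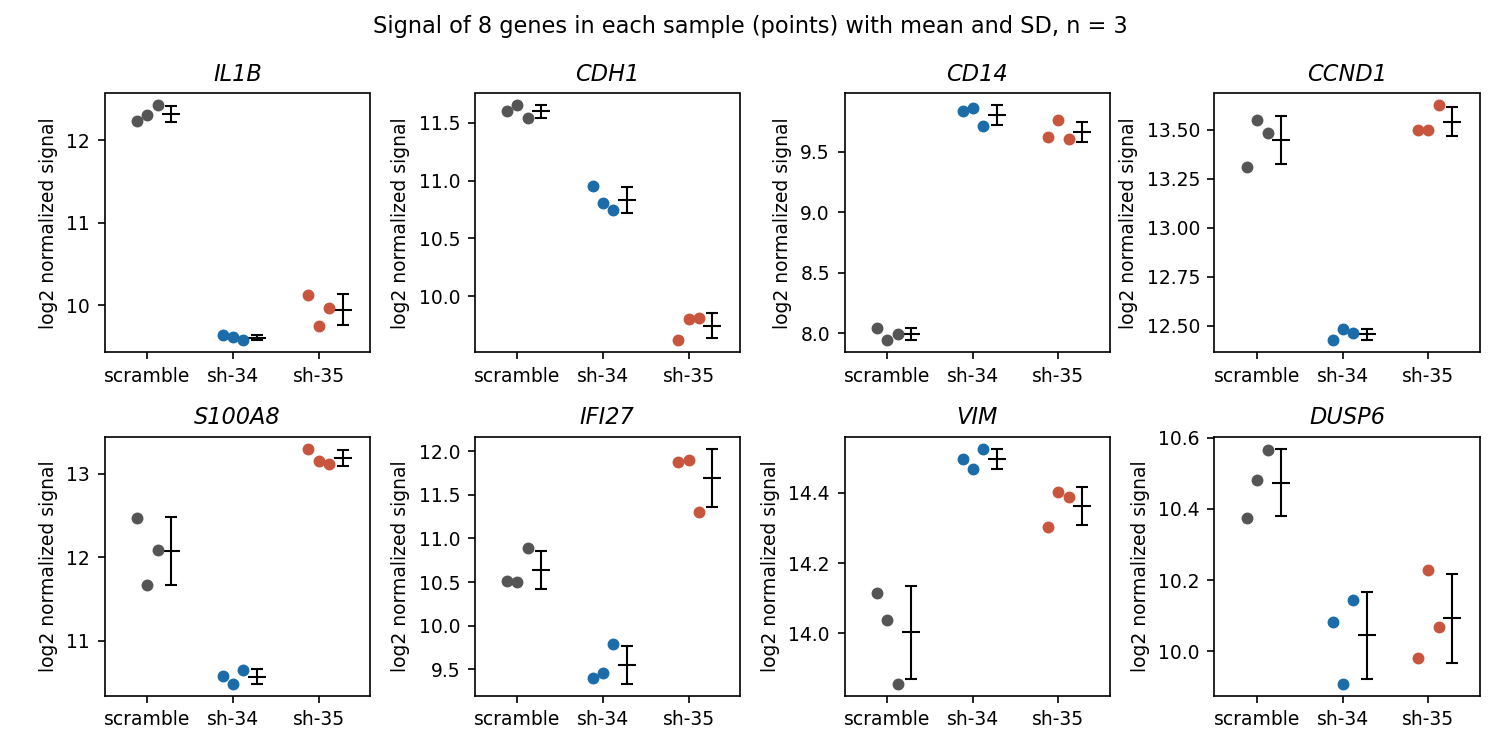
Normalized log2 signal (y axis) of 8 genes, chosen for display after their values were seen, in each of the 3 samples per group (points), with the group mean and SD (bars). CDH1 steps down from 11.60 in scramble to 10.83 with sh-34 and 9.74 with sh-35, and CCND1 is lower with sh-34 than with sh-35, a difference of +1.08 on the log2 scale.

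CD14 is also a marker of blood leukocytes, of whose list 5 genes were tested. LAPTM5 was at least 1.39-fold higher with sh-34, ITGB2, an integrin gene, rose by +0.53 with sh-34 (SE 0.08) and fell by 1.05 with sh-35 (SE 0.08), CSF1R fell by 0.73 with sh-34 (SE 0.14), and CD68 fell by 0.54 with sh-34 (SE 0.08). The leukocyte list had 2 of 5 higher and 3 lower for the mean of both hairpins (2 and 3 adjusted over the list alone; camera adjusted p = 0.706).

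For the mean of both hairpins against scramble, 13 of 32 tested lists were called, 5 higher and 8 lower. Cell cycle and mitosis genes rose, 44 of 47 higher, 0 lower and 3 not past (45 and 0 adjusted over the list alone), with a median of +0.73 (camera adjusted p = 2.3e-22, held at 0.0270 with an estimated correlation). Epithelial junction genes fell, 12 of 19 lower, 1 higher and 6 not past (13 and 1 adjusted over the list alone), with a median of −0.71 (camera adjusted p = 1.2e-05, held at 0.0270). Histone genes had 11 of 19 higher, 0 lower and 8 not past (12 and 0 adjusted over the list alone), with a median of +0.27 (camera adjusted p = 7.2e-05, held at 0.0321). Interferon response genes had 15 of 28 higher, 0 lower and 13 not past (15 and 0 adjusted over the list alone), with a median of +0.37 (camera adjusted p = 4.6e-05; adjusted p = 0.123 with an estimated correlation). IFIT2, an interferon-induced gene, rose with both hairpins, by +1.01 and +1.51 (SE 0.11). Cholesterol and fatty acid synthesis had 17 of 25 lower, 0 higher and 8 not past (17 and 0 adjusted over the list alone), with a median of −0.33 (camera adjusted p = 7.2e-05; adjusted p = 0.123 with an estimated correlation). HMGCS1 fell by 0.48 and 0.42 on the log2 scale (SE 0.09), and ELOVL6 by 0.67 and 0.56 (SE 0.08). Keratinocyte differentiation had 10 of 16 lower, 0 higher and 6 not past (10 and 0 adjusted over the list alone), with a median of −0.66 (camera adjusted p = 0.00022; adjusted p = 0.112 with an estimated correlation). Tested by hairpin, histone genes and keratinocyte differentiation were called with sh-34 and not with sh-35 (camera adjusted p = 0.539 and 0.157), and interferon response with sh-35 and not with sh-34 (0.224). Without the filter on dim probes the median was −0.19 for junction genes, +0.17 for histone genes and −0.0520 for keratinocyte differentiation, and these calls held.

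The other called lists of the mean of both hairpins lost their call with an estimated correlation. Hypoxia and glycolysis had 16 of 31 lower, 2 higher and 13 not past (18 and 3 adjusted over the list alone), with a median of −0.28 (camera adjusted p = 0.00079; adjusted p = 0.0720 with an estimated correlation), and ALDOC fell by 0.63 and 0.77 (SE 0.07). Ras-ERK output had 10 of 20 lower, 0 higher and 10 not past (10 and 0 adjusted over the list alone), with a median of −0.29 (camera adjusted p = 0.0010; adjusted p = 0.150 with an estimated correlation). HBEGF, PHLDA1 and IER3 fell with both hairpins, by 1.19, 0.64 and 0.66 with sh-34 and by 1.99, 0.90 and 0.40 with sh-35. Basal markers had 8 of 12 lower, 1 higher and 3 not past (8 and 1 adjusted over the list alone), with a median of −0.45 (camera adjusted p = 0.0011; adjusted p = 0.0720 with an estimated correlation), and DST, of the hemidesmosome, fell by 0.85 and 1.22 on its brightest probe (SE 0.14), with another DST probe at −0.26 for sh-34, not past. Luminal markers had 8 of 12 lower, 1 higher and 3 not past (8 and 1 adjusted over the list alone), with a median of −0.42 (camera adjusted p = 0.0104; adjusted p = 0.123 with an estimated correlation), and CD24 fell by 0.85 and 0.90 (SE 0.08). Senescence regulators had 6 of 8 higher, 1 lower and 1 not past (6 and 1 adjusted over the list alone), with a median of +0.37 (camera adjusted p = 0.0206; adjusted p = 0.171 with an estimated correlation). The metallothionein list had 4 of 6 higher, 0 lower and 2 not past (4 and 0 adjusted over the list alone). Its median was +0.38 (camera adjusted p = 0.0206, or 0.123 with an estimated correlation), and MT1G rose by +0.85 and +0.92 (SE 0.08). The actin cytoskeleton list had 12 of 28 lower, 2 higher and 14 not past (13 and 2 adjusted over the list alone), with a median of −0.13 (camera adjusted p = 0.0208; adjusted p = 0.366 with an estimated correlation), and without scramble replicate 2 its adjusted p was 0.0515 (median −0.0852). Of these lists Ras-ERK output was not called with sh-35 (camera adjusted p = 0.157), and senescence regulators, metallothioneins and the actin list were not called with sh-34 (0.224, 0.0839 and 0.263). Without the filter on dim probes the median was −0.16 for Ras-ERK output, −0.23 for basal markers, −0.0534 for luminal markers, +0.20 for senescence regulators, +0.0958 for metallothioneins and −0.0813 for the actin list, which read −0.21 with median scaling.

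**Figure D3:**
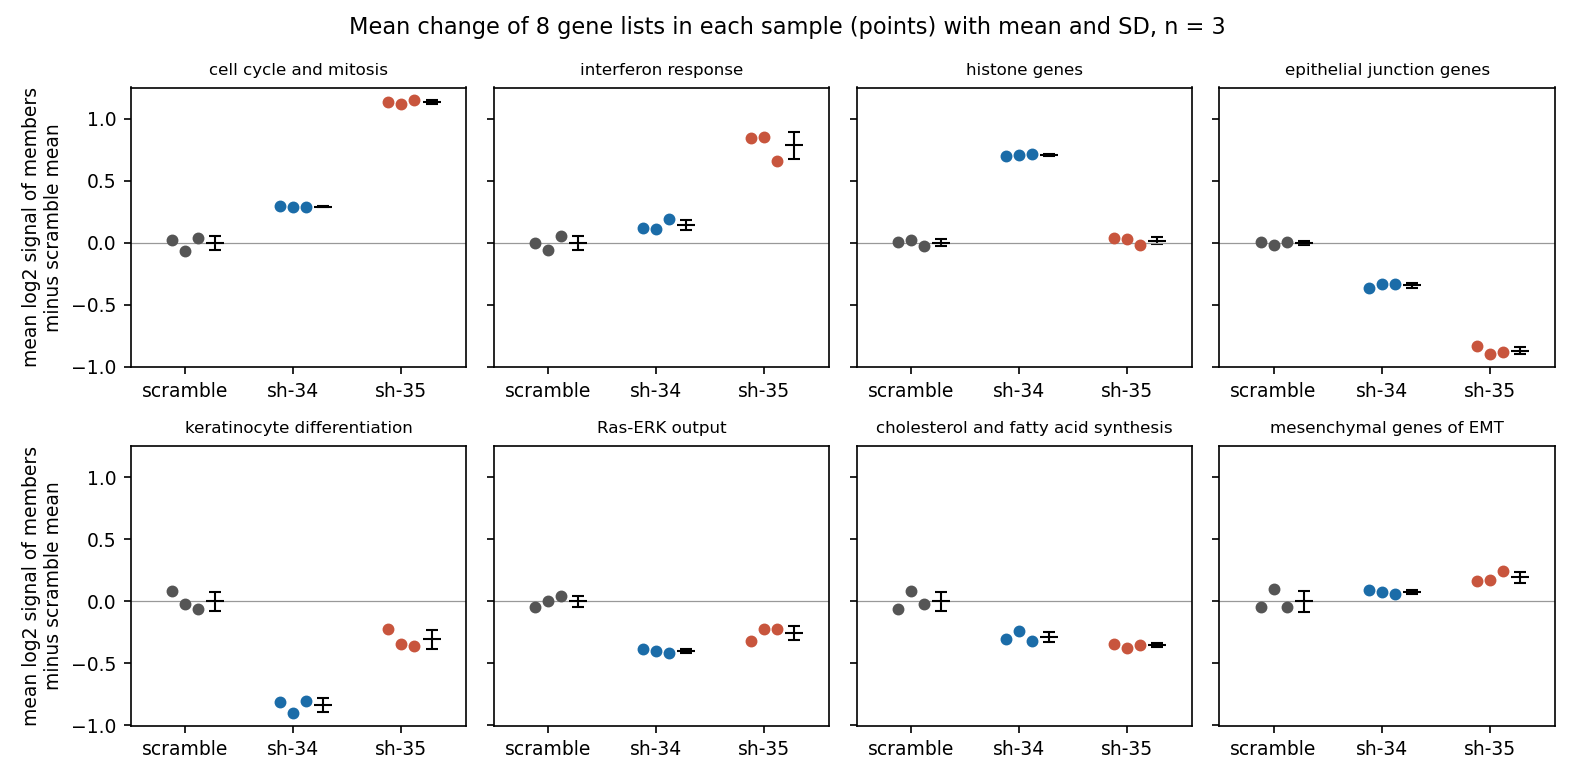
Mean log2 signal of the tested members of 8 gene lists in each sample, less the scramble mean (y axis), for the 3 samples of each group (points), with the group mean and SD (bars); the 8 lists were chosen for display after their values were seen. Cell cycle and mitosis genes lie near +0.29 with sh-34 and near +1.14 with sh-35, and epithelial junction genes near −0.34 and −0.87.

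In the same direction with both hairpins, 1611 genes passed the threshold, 848 higher and 763 lower, against 698.9 if the lists of the hairpins were independent. At least a 2-fold change with both was fitted for 81, 51 higher and 30 lower. The mean of both hairpins changed 3638 genes in limma, 1773 higher and 1865 lower. Both hairpins were compared with the same 3 scramble samples, so part of the excess may come from the shared controls, and 3 samples are too few to split. In 100 simulations of unchanged groups that shared controls, the mean number of shared genes was 0. Hardly any gene can pass where no group changes, so this count cannot say how much of the excess comes from the controls. The covariance of the fold changes was 0.00623 in the simulations (0.00586 to 0.00672), against 0.0882 observed. The simulated noise, drawn from the spread within groups, thus made up a small part of the observed covariance. A difference of the scramble group as a whole would enter both fold changes and is not in that noise. The covariance therefore cannot say how much of the agreement goes back to the scramble group. Pearson's r across genes was 0.475, just under the simulated range of 0.476 to 0.523 (mean 0.499). The same sign was found for 67.0% of genes, against a simulated 65.7% to 67.6% (mean 66.7%). Noise with shared controls gives about these levels whatever its size. Neither measure can therefore say how much of the agreement comes from the controls. Among the shared genes, 52.6% were higher, against 41.0% after median scaling, and for the mean of both hairpins 48.7% were, against 39.6%.

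The fourth comparison asked where the hairpins differed from each other. The contrast leaves out the scramble samples, which still entered the normalization, the probe filter and the estimate of spread. S100A8, a calcium-binding protein gene of inflamed epithelium, was higher with sh-35 than with sh-34, at 13.19 against 10.57 on the log2 scale, a difference of +2.62 (SE 0.16; limma adjusted p = 6.3e-07). PNKD differed by +2.57 (SE 0.10) on its brighter probe, but its second probe differed by −0.02. GXYLT1, a glycosyltransferase gene, differed by +2.40 (SE 0.09), IFI44L was at least 3.13-fold higher with sh-35, and WDR7 at least 2.6-fold higher (+1.69 on a second WDR7 probe). TAGLN was lower with sh-35, a difference of −2.81 (SE 0.09; adjusted p = 9.7e-09), as were TMEM9B at −2.38 (SE 0.11) and PPIAL4A at −2.20 (SE 0.10), the last a gene with near-identical paralogs. Histone gene H2BC4 was at least 2.79-fold lower with sh-35 and CST6, a cystatin gene, at least 1.71-fold lower.

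Cell cycle and mitosis genes were higher with sh-35 than with sh-34, 45 of 47 higher, 0 lower and 2 not past (46 and 0 adjusted over the list alone). Their median difference was +0.86 (camera adjusted p = 3.7e-23, held at 0.0291 with an estimated correlation), with HMMR at +1.65 (SE 0.12) and CDK1, the mitotic kinase gene, at +1.37 (SE 0.09). Interferon response genes were higher, 19 of 28, with 2 lower and 7 not past (19 and 2 adjusted over the list alone), at a median of +0.61 (camera adjusted p = 2.3e-05; adjusted p = 0.173 with an estimated correlation). IFIT3 differed by +1.79 (SE 0.13) and TRIM22, which fell with sh-34 and rose with sh-35, by +1.33 (SE 0.12). Epithelial junction genes were lower, 13 of 19, with 2 higher and 4 not past (13 and 2 adjusted over the list alone), at a median of −0.44 (camera adjusted p = 0.00063; adjusted p = 0.0615 with an estimated correlation). CDH1 differed by −1.09 (SE 0.09; limma adjusted p = 2.9e-06) and EPCAM by −1.37 (SE 0.08), whereas DSC2 was higher with sh-35 by +0.52 (SE 0.09). Histone genes were lower, 12 of 19, with 3 higher and 4 not past (12 and 3 adjusted over the list alone), at a median of −0.78, or −0.67 with undetected members at their bound (camera adjusted p = 0.00093; adjusted p = 0.0615 with an estimated correlation). With dim probes kept, the median was +0.30 for interferon response and −0.20 for junction genes.

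Genes of inflammation and the squamous surface were higher with sh-35 than with sh-34. The NF-kB list had 12 of 19 higher, 2 lower and 5 not past (12 and 3 adjusted over the list alone), at a median of +0.34 (camera adjusted p = 0.0097; adjusted p = 0.173 with an estimated correlation). CSF3, encoding a colony-stimulating factor, was lower with sh-34 than with sh-35, a difference of +1.43 (SE 0.10), and CXCL1 differed by +1.18 (SE 0.10). Secreted proteases and inhibitors had 11 of 22 higher, 2 lower and 9 not past (11 and 2 adjusted over the list alone), at a median of +0.20 (camera adjusted p = 0.0271; adjusted p = 0.173 with an estimated correlation). SERPINE2 differed by +1.06 (SE 0.08), SLPI by +1.03 (SE 0.10) and the cathepsin gene CTSB by +1.01 (SE 0.08). Keratinocyte differentiation genes had 8 of 16 higher, 2 lower and 6 not past (9 and 2 adjusted over the list alone), at a median of +0.36, or +0.43 with undetected members left out. The keratinocyte camera adjusted p was 0.0381 (adjusted p = 0.391 with an estimated correlation), and its call was lost without the filter on dim probes (0.0553), without sh-34 replicate 2 (0.0887) and without sh-35 replicate 1 (0.0859). S100A9, the partner of S100A8, differed by +1.72 (SE 0.17) and PI3 by +1.60 (SE 0.10). The actin cytoskeleton list had 9 of 28 lower, 2 higher and 17 not past (9 and 2 adjusted over the list alone), at a median of −0.15 (camera adjusted p = 0.0322; adjusted p = 0.522 with an estimated correlation), and without sh-35 replicate 3 its adjusted p was 0.0534. Without the filter on dim probes the median was +0.22 for NF-kB genes, +0.11 for proteases, +0.0654 for keratinocyte differentiation and −0.10 for the actin list.

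Ras-ERK output was not called between the hairpins, with 10 of 20 higher, 4 lower and 6 not past (11 and 4 adjusted over the list alone; camera adjusted p = 0.201). Single members differed, CCND1 by +1.08 (SE 0.08; limma adjusted p = 2.3e-06), TGFA by +0.68 (SE 0.08), HBEGF by −0.80 (SE 0.09), SPRY4 by +0.57 (SE 0.09; adjusted p = 0.00041) and ETV5 by +0.34 (SE 0.08; adjusted p = 0.0037), for which a second ETV5 probe gave +0.27 and did not pass. SPRY4 itself read −0.29 with sh-34 and +0.29 with sh-35 against scramble (adjusted p = 0.028 and 0.025). These SPRY4 calls were lost in 5 and 6 alternatives, with adjusted p from 0.0684 to 0.101 and from 0.0518 to 0.208. FOSL1 differed by +0.28 (adjusted p = 0.032), a call lost in 6 alternatives with adjusted p from 0.0518 to 0.122. Among the mesenchymal genes, FN1 differed by +0.80 (SE 0.14; adjusted p = 0.00077), and CDH2, VIM, SNAI2 and TWIST1 did not pass.

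Between the hairpins 3814 of 8931 genes (42.7%) passed the threshold in limma, 1852 higher with sh-35 and 1962 lower. A fitted difference of at least 2-fold was found in 373, 248 higher and 125 lower. The share higher with sh-35 was 48.6%, against 60.4% in the series matrix values. With 2012 genes read by more than 1 tested probe, probes of the same gene passed in opposite directions for 11 genes with sh-34, 18 with sh-35 and 16 between the hairpins.

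The authors' own deposited list of changed probes held 358 probes, 313 of them named here, with 152 higher with both hairpins, 186 lower with both and 20 in opposite directions. Every one of them changed at least 1.4-fold with both hairpins in the authors' ratios. These were computed on the deposited signals without further normalization between arrays. Of these probes, 340 were tested here, and 340 had the same sign and passed the threshold with both hairpins. The authors' list holds the probes of the same arrays within limits of fold and p-value with both hairpins. Whether the authors set the limit on adjusted or unadjusted p-values is not given in the sources used here. This overlap was therefore largely built in and is no independent support. In the authors' signed fold changes, IL1B was lowest with sh-34 at −6.85, followed by CA12 at −4.94, HAS3 at −4.78, FOLR3 at −4.70 and KRT14 at −3.78. The highest with sh-34 were KLRC3 at 5.19, KLRC2 at 4.46, the small nuclear RNA gene RN7SK at 4.22 and 3.32 on a pair of probes, and NWD1 at 3.88. With sh-35 the lowest were TAGLN at −10, IL1B at −5.34, CRB3 at −3.95, FOLR3 at −3.82 and CDH1 at −3.73, and the highest SERPINA5 at 6.08, KLRC3 at 4.01, EVI2B at 3.61, MAMDC2 at 3.58 and MLPH at 3.48.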

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

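The list tests were planned, and the tests of explanations for the cell cycle and interferon genes were chosen only after the result was seen. The test for silencing of other transcripts was written beforehand for both hairpins jointly and was split by hairpin before its shares were computed; its 5 alternatives of normalization and background were added after.

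Cell cycle and mitosis genes differed between the hairpins, with a median log2 difference of 0.86, higher with sh-35 in 45 of 47 genes. The quantile normalization used here is argued against as the source. The list's median less that of all genes was 0.848 in the series matrix values, to which it was not applied. A shift of all genes of like brightness is argued against too, since the highest median of 10000 random lists of the same size and level was 0.209. No biological explanation was tested. Whether the difference goes back to RND1, to the hairpin sequence or to the state of the cultures at harvest stays open, since each hairpin stands for 1 group.

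Interferon response genes also differed between the hairpins, with a median log2 difference of 0.61. The list's call was lost with an estimated correlation (adjusted p = 0.173). A shift of all genes of like brightness is argued against by random lists of the same size and level, whose highest median was 0.352. Unequal loss of RND1 may also lie behind it and cannot be told apart from an effect of the hairpin sequence, since the RND1 probe was above background on 0 scramble arrays. A reaction to the vector of unequal strength was not tested.

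Some large changes with 1 hairpin came with little change with the other, in 62 of the 258 genes changed at least 2-fold with sh-34 and in 113 of the 456 with sh-35 (under 1.2-fold and not past the threshold with the other hairpin). Of the 62 with sh-34, 54 fell, or 87.1% (exact 95% interval 76.1% to 94.3%, above 50% in all 5 alternatives), against 57.4% of the 258, which include the 62. This met the condition set beforehand for direct silencing of other transcripts by sh-34 as the main source. The interval, like that for sh-35, takes genes as independent, which genes that change together are not. Indirect falls would give the same share, so the test cannot decide for direct silencing by sh-34, which stays a hypothesis. For sh-35, 45 of the 113 fell, or 39.8% (30.7% to 49.5%), against 37.9% of the 456. The interval lay under 50%, the condition set beforehand against silencing by sh-35 as the main source. It also did with cyclic loess, median scaling and the series matrix values but reached 51.6% with an offset of 50 and 51.3% without background correction. The share itself was 35.8% to 40.6% in the alternatives. Since 68 of the 113 rose, the values argue against direct silencing by sh-35 as the main source for these genes. The test itself was counted as undecided for sh-35, since the interval did not stay under 50% in every alternative. Silencing of some of the 45 that fell was not tested. Read jointly, as first written, the test came out undecided, and seed matches of the hairpins were not tested.

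Other lists also differed between the hairpins by the test of the difference itself. The median log2 difference, sh-35 minus sh-34, was −0.44 for epithelial junction genes, 0.34 for NF-kB genes, 0.36 for keratinocyte differentiation, −0.15 for the actin cytoskeleton, 0.20 for secreted proteases and inhibitors and −0.78 for histone genes. These 6 calls were lost with an estimated correlation, at adjusted p = 0.0615, 0.173, 0.391, 0.522, 0.173 and 0.0615 in that order. Opposite calls against scramble were found for 274 genes, and 1611 were called in the same direction. Both hairpins were set against the same scramble samples, which favours calls in the same direction. These counts therefore do not measure how far the hairpins agree. Of the 274, 135 were higher with sh-34 and lower with sh-35 and 139 went the other way. Among those above background on at least 1 array of every group, 2 changed at least 2-fold both ways: S100A8, with a difference of 2.62, and IFI27, with 2.15, named here because so few met that limit. SPRY4, a feedback inhibitor gene of ERK signalling, also went opposite ways, with a difference of 0.57.

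Probes without a gene name were not counted in the comparisons. Of 1565 tested, 251 changed in the same direction with both hairpins (16.04%), 135 higher and 116 lower, against 16.72% of 11301 named probes.

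Other splits of the samples were counted for each number of changed genes. With 3 samples against 3 there are 10 splits, too few for a share under 0.05; in 1 of 10, the real one, the count was as large, with 3347 genes for sh-34, 3731 for sh-35 and 3814 between the hairpins, and the highest of the other splits gave 0 each time. For the mean of both hairpins, 1 of 100 splits of the 9 samples, the real one, gave as many as the real 3638, the highest other being 2103. For genes shared by both hairpins, 1 of 100, again the real one, gave as many as the real 1611, the highest other being 1243. Both shares are under 0.05, the limit set beforehand, which argues against a chance division of these samples. The labels do not say whether the samples of a group were separate cultures or were infected separately. With repeats of 1 culture, the splits would set the groups against technical spread only. With cultures from 1 infected pool, each hairpin would still be 1 case. Groups of 3 were not tested for samples far from the others.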

How the results depend on the processing

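Reading RND1 at a detection p under 0.05 was chosen after seeing the data, as were the 5 alternatives for the share that fell with 1 hairpin, and gave 0 arrays; the normalization alternatives give no RND1 value, and the slide as a block was not run because no slide is given. Counts of changed genes stayed within 1.5 times in all other settings run except the fold limits, which remove genes by construction. At least 1.5-fold, the counts were 1050 for sh-34, 1393 for sh-35, 929 for the mean of both, 1359 between the hairpins and 367 shared; at least 2-fold they were 258, 456, 198, 373 and 81. Leaving out each replicate in turn gave 2755 to 3371, 3234 to 3682, 2939 to 3504, 3228 to 3821 and 1304 to 1519. From the series matrix values the counts were 2695, 3182, 3118, 3032 and 1279, and with every probe on its own 4477, 5045, 4911, 5038 and 2141 probes. With the replicate number as a block the counts were 3295, 3688, 3543, 3770 and 1579. Called lists numbered 9, 13, 13 and 8 (sh-34, sh-35, mean of both, between hairpins), and with camera's estimated correlation 1, 2, 3 and 1, while fry, which does not compare a list with other genes, called 25, 22, 22 and 24. Without single replicates the lists called were 9 to 10, 12 to 14, 13 to 13 and 7 to 8. Reversed results were TGF-beta targets between the hairpins with fry (median 0.0425, limma adjusted p = 0.0043, direction down), and with the mean of a gene's probes NRG1 with sh-34 (−0.32), INSIG1 with sh-35 (−0.48) and INSIG1 between the hairpins (−0.0678); probes of NRG1 and INSIG1 differ, and the cause was not tested. Of 1026 gene results, 71 lost their call with median scaling and 81 with the series matrix values. Genes near background are limited by signal, RND1 among them.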

Other observations

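Several lists not called in any comparison still held genes that changed. Among HER family ligands and receptors, 2 of 8 rose, 5 fell and 1 did not pass for the mean of both hairpins (2 and 5 adjusted over the list alone; camera adjusted p = 0.191). LRIG1, a feedback inhibitor of the EGF receptor, rose by +0.74 with sh-34 and +0.92 with sh-35 (SE 0.09), while EGFR read −0.59 with sh-34 (SE 0.08) and −0.08 with sh-35 on its brighter probe, its other probe reading −0.19 with sh-34 and not passing (adjusted p = 0.368). Of plexins, semaphorins and Ras-like GTPases, 3 of 19 rose, 3 fell and 13 did not pass (3 and 3 adjusted over the list alone; camera adjusted p = 0.487), with SEMA3F lower by −0.83 and −0.52 (SE 0.08) and RAP1B, a Ras-like GTPase gene, lower by −0.46 and −1.12 (SE 0.10). Integrins, laminins and collagens had 10 of 27 higher, 6 lower and 11 not past (10 and 6 adjusted over the list alone; camera adjusted p = 0.277). The basement membrane collagens COL4A1 and COL4A2 rose with both hairpins, by +0.69 and +0.65 (SE 0.10) and by +0.89 and +1.2 (SE 0.18), while the integrin gene ITGA2 fell by 0.65 and 0.66 (SE 0.09).

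Targets of p53 had 7 of 23 higher, 3 lower and 13 not past (7 and 3 adjusted over the list alone; camera adjusted p = 0.350), with RRM2B at +0.92 and +0.84 (SE 0.15) and SESN1 at +0.59 and +0.58 (SE 0.09). TGF-beta targets had 4 of 20 higher, 7 lower and 9 not past (4 and 7 adjusted over the list alone; camera adjusted p = 0.403), YAP-TEAD targets 7 of 19 higher, 4 lower and 8 not past (7 and 4; 0.487), with CCN1 at −0.80 and −1.12 (SE 0.10), and Wnt and Notch genes 5 of 18 higher, 5 lower and 8 not past (5 and 5; 0.989). Unfolded protein stress had 7 of 26 higher, 9 lower and 10 not past (8 and 9; 0.403), NRF2 targets 7 of 20 higher, 6 lower and 7 not past (7 and 6; 0.989), and apoptosis regulators 5 of 21 higher, 6 lower and 10 not past (6 and 6; 0.706). BCL2L1, which restrains apoptosis, fell with sh-35 by 1.08 on the log2 scale (SE 0.10) and read +0.31 with sh-34. Ribosomal proteins had 6 of 43 higher, 1 lower and 36 not past (5 and 1; 0.393), and the respiratory chain 3 of 34 higher, 2 lower and 29 not past (1 and 2; 0.572). The list for shRNA and microRNA processing had 2 of 12 higher, 3 lower and 7 not past (2 and 3; 0.956), with XPO5, which exports hairpin precursors, at −0.54 and −0.61 (SE 0.08). Fibroblast markers had 0 of 3 higher, 2 lower and 1 not past (0 and 2; 0.459). Endothelial, adipocyte and packaging cell markers had 2, 1 and 2 tested members and were not tested as lists. For the mean of both hairpins the median and the mean of the members differed in sign in the lists of Wnt and Notch genes (−0.07 and +0.01), NRF2 targets (−0.10 and +0.04), secreted proteases and inhibitors (−0.03 and +0.07) and leukocyte markers (−0.22 and +0.43), none of them called. The list of NF-kB genes, not called there either, had a median of +0.37 and a mean of +0.04; fry, which did not call it (adjusted p = 0.355), gave a downward direction.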
